A study of Homo sapiens with 18 samples.

How the data were processed

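RNA was measured in 18 libraries of MEG-01, a human megakaryoblastic leukemia cell line (Meg01 in the labels). Cells whose genotype label is WT, called unedited cells here, and cells labelled as an ETV6 knockout were each transduced with 1 of 3 lentiviral vectors: an empty vector (EV), ETV6, or ETV6 carrying R369W. Cells were harvested on day 3. Each of the 6 groups held 3 libraries, which the titles number 2, 3 and 4 in unedited cells and 1, 2 and 4 in knockout cells. What these numbers stand for is not given in the sources used here, and they are called replicate numbers. Per the labels, RNA was isolated with TRIzol and libraries were made by the Illumina TruSeq stranded mRNA protocol.

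The deposited table holds raw counts, whole reads per gene, for 1 library per column, with 5 further entries for reads given to no gene. The authors' processing notes name HISAT2, SAMtools and HTSeq without versions, and the GRCh38 genome build. The annotation and the strand setting of the counting are not given in the sources used here. Of the 20833 gene identifiers, 20801 matched a symbol in the gene name table used and 31 more were named from GENCODE release 29, which also gave the positions. Genes with close relatives or copies elsewhere in the genome (CD24, the globins, HLA, GYPB, and IFITM2 with IFITM3) may share reads, and their levels carry that uncertainty. A second deposited file lists libraries and totals only and was not used.

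Gene reads ran from 12577816 to 18927506 per library. A further 34.4% to 41.6% of the listed reads were given to no gene: 17.7% to 22.4% fell on no feature, 10.1% to 16.5% were not uniquely aligned, 1.84% to 4.68% had a low alignment quality and 0.765% to 3.30% were ambiguous. A count of 0 in a library allows up to 0.158 to 0.239 CPM (reads scaled to library size), taking 3 reads as the limit. This limit and the 95% intervals of ratios cover counting error only, because PCR reads without molecular identifiers are not independent molecules. Groups whose reads summed to 1 to 3 are given as a ratio of summed reads, scaled by library size, with an exact conditional binomial interval. Against a group with 0 reads the fold is a lower bound that takes 3 reads over the group.

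Differential expression was tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr on the group (12262 genes), scaled by TMM, and fitted with a quasi-likelihood model of 1 mean per group over all 18 libraries. The test was the two-sided quasi-likelihood F test, and p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The standard error (SE) of a log2 fold change is its size divided by the square root of F. The 7 comparisons of 2 groups and 3 interactions between vector and genotype, the gene lists and the rule for naming genes were fixed before the data were examined. The rule takes ETV6; the 8 largest rises and 8 largest falls per comparison among genes past the threshold with a mean log2 CPM of at least 1, a gene symbol, and all 3 libraries of 1 group above all 3 of the other; up to 4 members of each list with the smallest adjusted p past the threshold; and the 5 largest interactions in each direction. Every gene named as one of these rises or falls therefore shows its direction in all 6 libraries compared. An exact permutation test of 3 against 3 libraries cannot go below p = 0.1, so single values were tested in the edgeR model only.

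24 gene lists were written from textbook knowledge and 23 were tested, since the table holds no gene of the mitochondrial genome. Lists were tested with camera in limma 3.58.1 on voom values of the same model, with a preset correlation of 0.01 between genes and adjustment over the lists of a comparison. Companions were camera with an estimated correlation, which gives 1 p per list without the preset, and fry, whose values are not given here. The count filter kept 15 of 35 myeloid, 6 of 18 B-lymphoid and 7 of 14 endothelial genes. It can keep a gene through only the group where that gene is high, so the medians of these lists describe the kept members only. Members past the threshold were counted over all genes and adjusted over the list alone. Medians were also taken with low-count genes at their bound.

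Pairing by replicate number was checked from correlations across genes of each library's deviation from its group mean; genes are not independent replicates, and these are descriptions. In unedited cells, same-numbered libraries of different vectors correlated at 0.695 to 0.856, and differently numbered ones at -0.583 to 0.0424. In knockout cells, same-numbered EV and ETV6 libraries correlated at 0.763 to 0.847, against -0.619 to -0.133 for others. Knockout R369W libraries correlated at -0.581 to -0.153 with the same-numbered libraries of the other vectors, so no block was fitted to them outside the alternatives. A fit with the replicate number as a block was therefore added after the data were seen, for the 9 unedited libraries and for the 6 knockout EV and ETV6 libraries. Its common dispersion was 0.00321 and 0.00391, against 0.0592 in the fit of 18 libraries without a block. The 2 numbers that both genotypes share were used as 1 block only in the alternative over all 18 libraries, and there only for knockout against unedited EV cells; elsewhere in it the block was the number within each genotype.

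The fitting code was tested on simulated data, drawn from a negative binomial with the means and dispersions of the real genes and 200 changed genes. For knockout against unedited EV cells edgeR recovered 64.95% of genes with a simulated log2 change of 1 and 80.61% with a change of 2, with 4 false among 146 calls; for knockout R369W against ETV6 it recovered 54.55% and 80.0%, with 3 false among 137. DESeq2 made 29 false among 180 calls and 34 among 181. A list raised by 0.8 on the log2 scale was the 1 list called of 23. Genes and libraries were drawn independently. The simulation therefore does not test the preset correlation of camera, nor the correlation of same-numbered libraries seen in the real data.

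Alternatives were DESeq2 size factors, no filter, a stricter filter (CPM over 5 in at least 3 libraries), the DESeq2 1.42.0 Wald test, limma-voom, a fit of the compared groups alone, the replicate number as a block in all 18 libraries, leaving out the knockout libraries numbered 4 and 10 (whose library numbers are out of the order of their groups), and leaving out each library in turn. Added after the data were seen were the block on paired libraries only and 4 surrogate variables from sva 3.50.0. Libraries were left out only in the fit without a block, so lost calls include the spread between replicate numbers. Overlaps of 7 pairs of comparisons were set against the product of the counts over the genes tested, and, where libraries were shared, against 20 simulations of unchanged groups, with either the dispersion between lines or that within them. Principal components were taken from log2 CPM. Dixon's test for outlying libraries was not run on these groups of 3. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.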

Results

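The series asks how the ETV6 p.R369W variant acts in a megakaryocytic cell line, by adding ETV6, ETV6 R369W or an empty vector (EV) to unedited and ETV6 knockout MEG-01 cells. ETV6 is a transcriptional repressor of the ETS family. Messenger RNA was counted in 18 libraries, 3 in each of the 6 groups, on day 3 after transduction. Of these, 16 libraries held between 12577816 and 13551477 gene reads, unedited EV replicate 4 held 16041684 and knockout EV replicate 1 held 18927506. Reads that did not align made up 0.527% to 0.809% of the 6 EV libraries and 0.279% to 0.349% of the other 12, so the EV libraries stood apart in this measure in both genotypes.

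ETV6 itself (ENSG00000139083, GRCh38 chromosome 12, 11649854 to 11895402, plus strand) was raised by both vectors to a similar level. It averaged 96.3 ± 42.7 CPM (reads scaled to library size; SD, n = 3) in unedited EV cells, 2440 ± 161 with ETV6 and 2541 ± 425 with R369W. In knockout cells the means were 85.1 ± 40.7, 1969 ± 354 and 1692 ± 372. The rise over EV was 4.66 on the log2 scale with ETV6 and 4.72 with R369W in unedited cells (SE 0.39 for each, adjusted p = 3.52e-05 and 4.48e-05), and 4.53 and 4.31 in knockout cells (SE 0.38 for each, adjusted p = 8.69e-06 and 1.18e-04). R369W and ETV6 cells differed by 0.06 (SE 0.33, adjusted p = 1) in unedited cells, or by -0.03 without unedited R369W replicate 3, and by -0.22 (SE 0.33, adjusted p = 0.873) in knockout cells. Between knockout and unedited EV cells the difference was -0.18 (SE 0.34, adjusted p = 0.845), and it turned to 0.24 without unedited EV replicate 4 and to 0.16 without knockout EV replicate 2. Gene counts do not separate the vector's transcript from the cell's own, nor R369W from ETV6, nor do they show an edit, so the knockout label was neither checked nor contradicted by them.

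**Figure D1:**
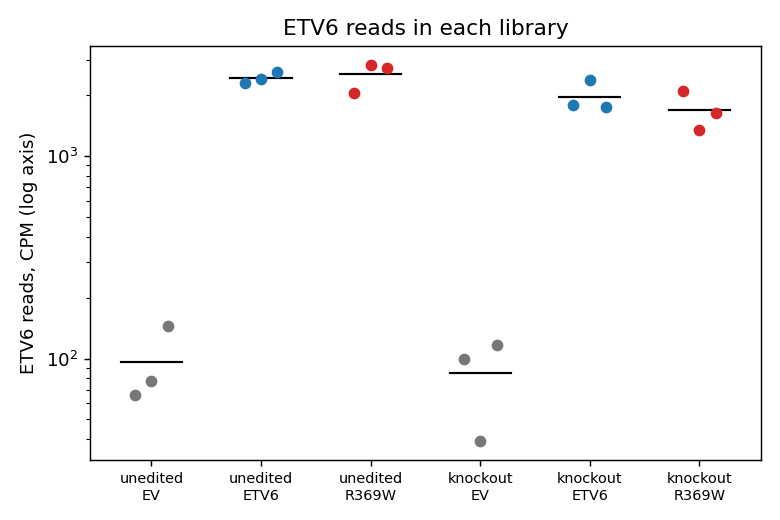
ETV6 reads in CPM (log axis) in each of the 18 libraries, with a point per library and a line at the mean of each group. The means lie at 96.3 and 85.1 CPM in the EV groups and between 1692 and 2541 CPM in the 4 groups given ETV6 or R369W.

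ETV6 against EV in unedited cells asks what more ETV6 does. CD24, a surface glycoprotein of developing B cells, dropped 5.96-fold from 249 ± 103 to 41.8 ± 10.4 CPM (SD, n = 3; log2 -2.58, SE 0.31, adjusted p = 0.00117). RINL, a Ras and Rab interactor-like protein, fell 4.44-fold from 26.6 ± 2.11 to 5.98 ± 0.621 CPM (adjusted p = 3.52e-05). CD33, a myeloid sialic acid receptor, fell 2.31-fold from 327 ± 42.7 to 142 ± 9.62 CPM (adjusted p = 1.13e-04). WAS, which links small GTPases to actin, fell 2.05-fold (adjusted p = 0.00452), and NBEAL2, needed for platelet alpha granules, fell 1.60-fold (log2 -0.68, SE 0.11, adjusted p = 0.0103). ICAM1, an adhesion molecule, ITGAM, an integrin of myeloid cells, and KCNK6, a potassium channel, fell 3.76-fold, 2.49-fold and 2.43-fold (adjusted p = 0.0413, 0.0217 and 0.00658). DIAPH1, an actin-nucleating formin, rose by 0.31 on the log2 scale (SE 0.06, adjusted p = 0.0397).

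In all, 37 of 12262 genes passed in this comparison, 2 higher (ETV6 and DIAPH1) and 35 lower. With the replicate number as a block in the 9 unedited libraries, 956 passed, 312 higher and 644 lower, among them all 37. Without a block the count was 24 without unedited EV replicate 2, 11 without EV replicate 3, 16 without ETV6 replicate 2 and 17 without ETV6 replicate 3. The calls of ICAM1, ITGAM and DIAPH1 were each lost without 5 of the 6 libraries in turn (adjusted p up to 0.268, 0.148 and 0.213; ICAM1 held without ETV6 replicate 4, the others without EV replicate 4). NBEAL2 was lost without EV replicate 3 (adjusted p = 0.0853) or ETV6 replicate 4 (0.0525), and KCNK6 without EV replicate 3 (0.0522).

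Of the fixed lists, the myeloid list was lower as a set: 2 of its 15 tested genes fell, CD33 and ITGAM, with 3 lower adjusted over the list alone, and the median log2 change was -0.51 (-0.53 with low-count genes at their bound). Its camera adjusted p was 1.38e-04, and adjusted p = 0.0864 with an estimated correlation. Of 6 B-lymphoid genes, CD24 fell, also adjusted over the list alone, and the list was lower (median -0.59, or -0.81 with bounds; adjusted p = 0.00337, and adjusted p = 0.0864 with an estimated correlation). The endothelial list of 7 genes was lower (median -0.33, adjusted p = 0.00337, and adjusted p = 0.56 with an estimated correlation), while edgeR called 0 of its genes over all genes, 1 adjusted over the list alone, and 2 at an unadjusted p under 0.05; DESeq2 and limma-voom called 0. That list was lost without EV replicate 4 (adjusted p = 0.0947) or ETV6 replicate 2 (0.0725). The stress list of 18 heat shock and immediate-early genes was higher (median 0.26, adjusted p = 3.17e-04, and adjusted p = 0.867 with an estimated correlation), as was cholesterol synthesis with 25 genes (median 0.16, adjusted p = 0.0177, and adjusted p = 0.935 with an estimated correlation). edgeR, DESeq2 and limma-voom called 0 genes of either, and adjusted over the list alone 0, with 5 and 0 at an unadjusted p under 0.05. Both were lost without EV replicate 4 (adjusted p = 0.563 for stress and 0.91 for cholesterol), ETV6 replicate 2 (0.0725 and 0.482) or ETV6 replicate 3 (0.0916 and 0.72), and the EV libraries of this comparison are those with more unaligned reads.

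R369W against EV in unedited cells asks what the variant does where the cell's own ETV6 remains. Besides ETV6, CLIC5, a chloride intracellular channel protein, and MYT1, a zinc finger transcription factor, were higher. CLIC5 rose from 0.247 ± 0.248 to 16.5 ± 11.6 CPM (SD, n = 3; log2 6.08, SE 0.74, adjusted p = 0.00738). MYT1 had 1 read in the EV group and 149 with R369W, a ratio of 169 (95% counting interval 29.8 to 6704). The 3 genes passed with 0 lower, against 248 at an unadjusted p under 0.05, 13 called by DESeq2 and 1 by limma-voom. With the replicate number as a block, 251 passed, 210 higher and 41 lower, including all 3. CLIC5 was lost without EV replicate 3 (adjusted p = 0.077) or EV replicate 4 (0.11), and 6 genes passed without R369W replicate 4.

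By camera 4 lists were called in this comparison, none with an estimated correlation. The myeloid list of 15 genes was higher (median 0.21, adjusted p = 4.35e-05, and adjusted p = 0.124 with an estimated correlation), with 0 members called by edgeR, 2 adjusted over the list alone, 2 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom. B-lymphoid genes had those same counts over 6 genes (median 0.60, or 0.45 with bounds; adjusted p = 0.0258, and adjusted p = 0.183 with an estimated correlation), and the list was lost without EV replicate 2 (adjusted p = 0.0936) or R369W replicate 4 (0.272). The interferon list of 43 genes was higher (median 0.10, adjusted p = 0.0258, and adjusted p = 0.706 with an estimated correlation), and the MYC and ribosome biogenesis list of 30 genes was lower (median -0.06, adjusted p = 0.0133, and adjusted p = 0.706 with an estimated correlation). All 3 tools called 0 genes of both, as did adjustment over the list alone, with 0 and 1 at an unadjusted p under 0.05. Both were lost without EV replicate 2 (adjusted p = 0.681 for each) or R369W replicate 4 (0.569 and 0.78), and interferon without R369W replicate 3 (0.199).

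R369W against ETV6 in unedited cells compares the variant with ETV6 at like ETV6 read levels. Higher genes included some that had passed as lower with ETV6 (CD24, RINL and ICAM1) and others that had not (IL6R, RASGRP4, CLIC5, MYT1, BIRC7, TNFSF10, IL7R and GP6). CD24 stood at 468 ± 140 CPM (SD, n = 3), 11.2-fold above ETV6 cells (log2 3.49, SE 0.32, adjusted p = 3.99e-05). RINL was 5.87-fold, ICAM1 6.47-fold and IL6R, a cytokine receptor, 6.35-fold higher (adjusted p = 3.11e-06, 0.00105 and 5.34e-04). RASGRP4, a Ras exchange factor, was 5.89-fold higher (adjusted p = 0.00713). CLIC5 had 619 reads against 0, at least 212-fold, MYT1 was at least 51.0-fold and BIRC7, an inhibitor of apoptosis, at least 34.6-fold higher. CLIC5, MYT1 and BIRC7 lay outside the naming rule in this comparison. They were chosen here after their values were seen and were not followed with libraries left out. TNFSF10, a death receptor ligand, IL7R, the interleukin 7 receptor, and GP6, the platelet collagen receptor, were 12.0-fold, 7.78-fold and 4.17-fold higher (adjusted p = 0.0115, 0.00992 and 0.00773). Lower with R369W than with ETV6 were GABPB1, a subunit of an ETS factor complex, by 0.51 on the log2 scale, NR2F2, an orphan nuclear receptor, by 0.83, and WNT7A, a secreted WNT ligand, by 2.25, among others (adjusted p = 0.00615, 0.0101 and 0.0379).

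Here 147 genes passed, 138 higher and 9 lower, and with the replicate number as a block 1980 passed, 1197 higher and 783 lower, including 145 of the 147. The count was 90 without ETV6 replicate 2, 92 without ETV6 replicate 3 and 93 without R369W replicate 3. TNFSF10 was lost without any of the 3 ETV6 libraries or R369W replicate 3 (adjusted p up to 0.0795), IL7R without ETV6 replicate 3 or 4 (0.0549 and 0.0645), GP6 and NR2F2 without ETV6 replicate 2 or 3 (up to 0.0592 and 0.0595), and WNT7A without each of the 6 libraries (up to 0.157). These losses belong to the fit without a block. With the block, chosen after the data were seen, each of these genes passed with all libraries in (edgeR adjusted p up to 1.22e-05).

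The myeloid list was higher with R369W than with ETV6: 3 of 15 genes were higher, 6 adjusted over the list alone, and the median was 0.75 (0.73 with bounds, camera adjusted p = 1.2e-07, and adjusted p = 0.0233 with an estimated correlation). The 3 were CD33 (3.00-fold, 425 ± 23.7 CPM), ITGAM (3.43-fold) and FCER1G, an Fc receptor chain (4.11-fold; adjusted p = 0.00167). Of 6 B-lymphoid genes, CD24 and RAG2, a recombinase of lymphocytes, were higher, also adjusted over the list alone (median 2.04, or 0.97 with bounds, camera adjusted p = 4.75e-04, and adjusted p = 0.0233 with an estimated correlation). RAG2 was 6.14-fold higher (edgeR adjusted p = 0.0111) and was lost without ETV6 replicate 3 or 4 (0.0595 and 0.0505). The interferon list was higher with 2 of 43 genes past the threshold, the membrane proteins IFITM2 (2.72-fold) and IFITM3 (3.47-fold), and 6 adjusted over the list alone (median 0.14, adjusted p = 0.0133, and adjusted p = 0.742 with an estimated correlation). IFITM3 was lost without 5 of the 6 libraries (adjusted p up to 0.182; it held without R369W replicate 2). Endothelial genes were higher (median 0.53, adjusted p = 0.00433, and adjusted p = 0.601 with an estimated correlation) and MYC and ribosome biogenesis genes lower (median -0.11, adjusted p = 4.75e-04, and adjusted p = 0.742 with an estimated correlation). edgeR called 0 genes of either, 3 and 0 adjusted over the list alone, 3 and 4 at an unadjusted p under 0.05, DESeq2 1 and 0, limma-voom 0. Without ETV6 replicate 2 these 3 lists had adjusted p = 0.508, 0.124 and 0.199, and without R369W replicate 4 they had 0.248, 0.157 and 0.157.

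**Figure D2:**
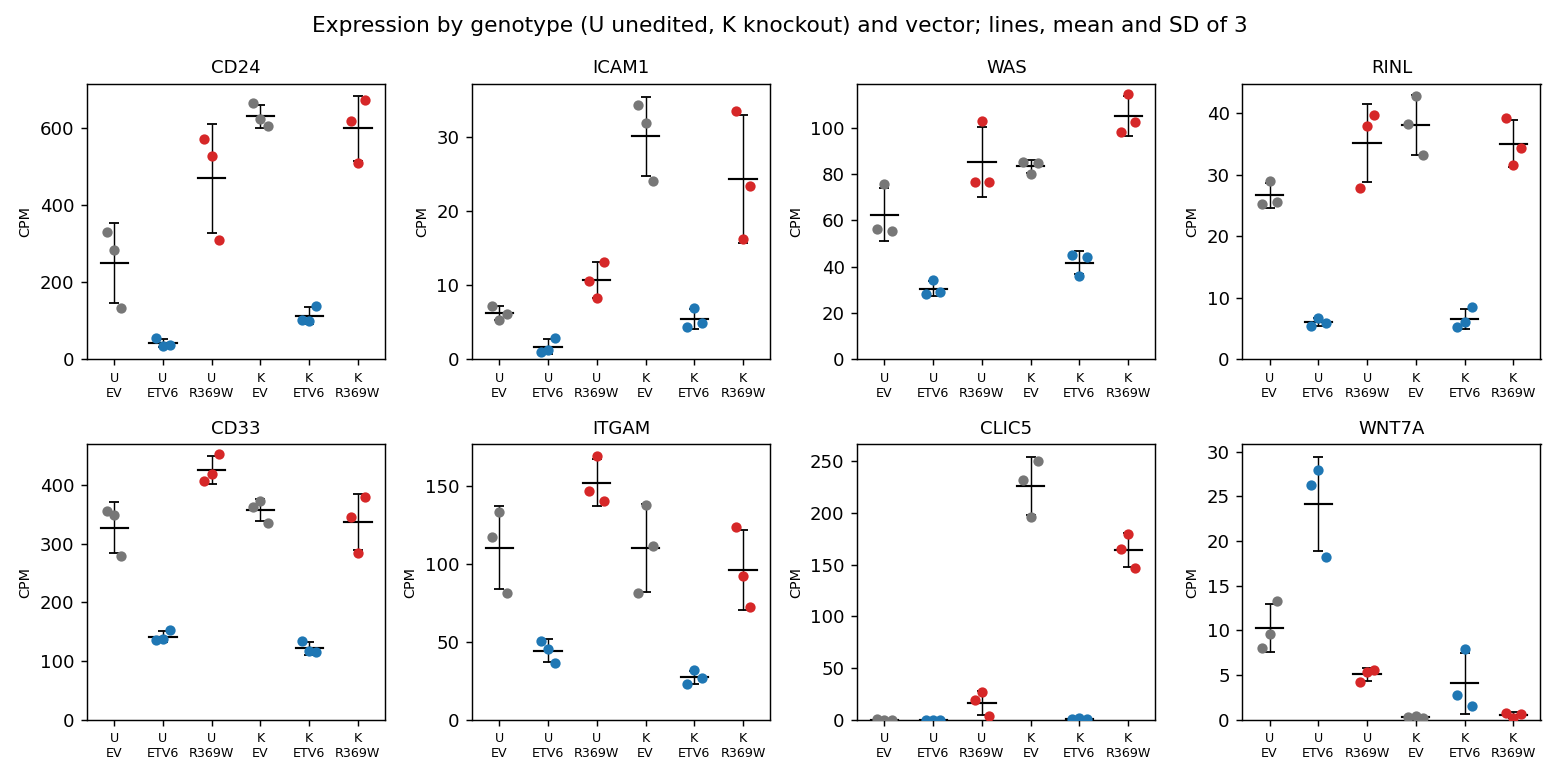
CPM of 8 genes in each library by genotype (U, unedited; K, knockout) and vector, with points for libraries and lines for the mean and SD of 3; each axis starts at 0. CD24, ICAM1, WAS, RINL, CD33 and ITGAM are lowest with ETV6 in both genotypes, CLIC5 reaches 226 CPM in knockout EV cells, and WNT7A peaks at 24.1 CPM in unedited ETV6 cells.

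Knockout against unedited cells, both with EV, asks what loss of ETV6 goes with. Genes that were almost silent in unedited cells were strongly expressed in the knockout. CLIC5 rose from 0.247 ± 0.248 to 226 ± 27.7 CPM (SD, n = 3; log2 9.85, SE 0.72, adjusted p = 8.63e-06), and LMTK3, a membrane kinase, rose from 0.121 ± 0.0519 to 51.1 ± 14.4 (log2 8.65, SE 0.70). BIRC7 had 2177 reads against 1, a ratio of 2048 (95% counting interval 367 to 80916). SLFN11, a protein of the DNA damage response, had a ratio of 2436 (437 to 96260), NOVA2, a neuronal splicing factor, 1784 (493 to 14735) and SHISAL1, a Shisa-like membrane protein, 1341 (240 to 53015). FYB1, a T cell and platelet adaptor, rose 152-fold (adjusted p = 3.48e-04). Falls included WNT7A, from 10.3 ± 2.71 to 0.325 ± 0.156 CPM (log2 -4.93, SE 0.62, adjusted p = 2.73e-04), S1PR1, a sphingosine phosphate receptor (11.9-fold, adjusted p = 2.03e-04), UNC5B, a netrin receptor (10.8-fold), and RASGRP3 (5.74-fold).

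In total 531 genes passed, 406 higher and 125 lower, with a median absolute log2 change of 1.28 and 314 over 2-fold. The count was 246 without unedited EV replicate 2, 341 without EV replicate 3, 346 without EV replicate 4, 290 without knockout EV replicate 1 and 277 without knockout EV replicate 4. On the first 2 principal components of all libraries, unedited EV replicate 4 (-10.8 and -48) and knockout EV replicate 2 (6.27 and 46.8) lay away from the other 2 libraries of their groups (-51.1 and -43.1, and 50.4 and 59.3, on the first). Libraries of the other vectors lay beside them: unedited ETV6 (-14.9 and -53.3) and R369W (-5.98 and -40.2) replicate 4, and knockout ETV6 replicate 2 (-1.65 and 33.2). Knockout R369W replicate 1 (9.31 and 47.8) also lay there, so the shift was not particular to EV libraries. Unedited cells carry the replicate numbers 2, 3 and 4 and knockout cells 1, 2 and 4. Whether a number in both names the same source is not given in the sources used here. Genotype was thus compared through only 3 libraries on each side. The error of this test came from all 18 libraries, in which same-numbered libraries of different vectors correlated, apart from knockout R369W, and were not independent. Fitted on these 2 groups alone, edgeR called 211 genes, 175 higher and 36 lower.

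**Figure D3:**
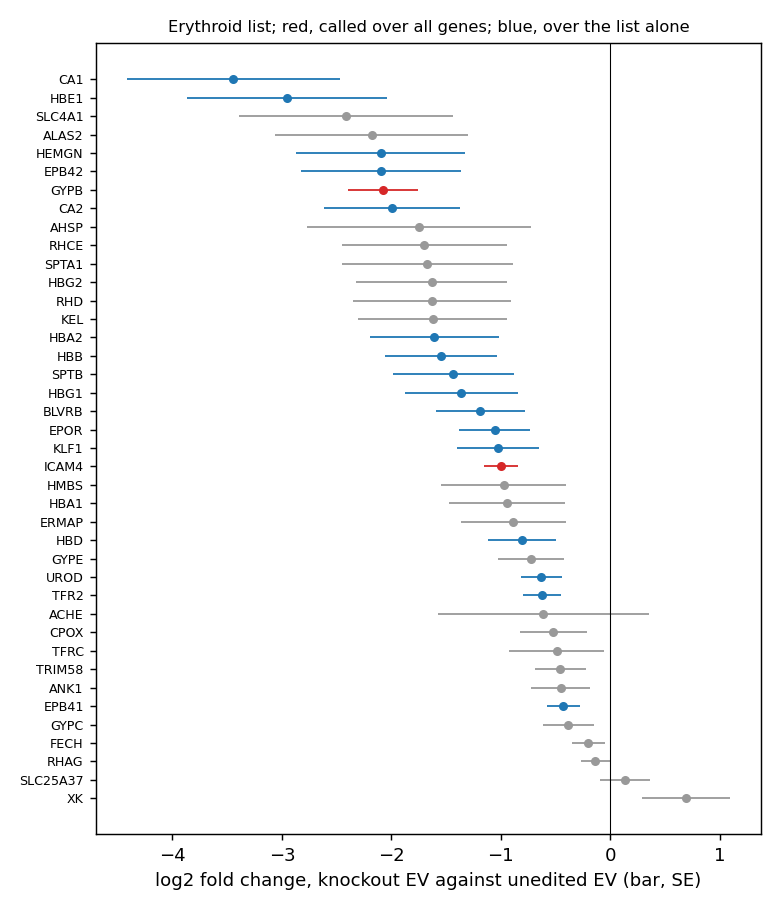
Log2 fold change of 40 of the 41 erythroid genes tested, knockout EV against unedited EV, with bars of 1 SE. Red genes (2 of those shown) passed over all genes, blue ones passed adjusted over the list alone, and the median of the 41 is -1.06.

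Erythroid genes were lower in the knockout as a set. Of 41 genes 3 fell, with 19 lower adjusted over the list alone, and the median log2 change was -1.06 (camera adjusted p = 1.63e-17, and adjusted p = 0.284 with an estimated correlation). GYPB, a red cell surface glycoprotein, fell 4.22-fold from 21.4 ± 1.81 to 5.08 ± 2.33 CPM (SD, n = 3; adjusted p = 0.00123), and ICAM4, a red cell adhesion protein, fell 2.00-fold (adjusted p = 0.00144). Antigen presentation genes were higher: 3 of 22 rose, 10 adjusted over the list alone (median 0.80, adjusted p = 1.17e-06, and adjusted p = 0.0918 with an estimated correlation). HLA-B, a class I antigen, rose 3.93-fold from 23.6 ± 7.37 to 93.1 ± 23.9 CPM (adjusted p = 0.00185). NLRC5, an activator of class I genes, and PSMB8, an immunoproteasome subunit, rose 2.04-fold and 2.03-fold, but each was lost without 4 libraries (unedited EV replicates 2 and 4, knockout EV replicates 1 and 4; adjusted p up to 0.135 and 0.152).

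Some myeloid and B-lymphoid genes were higher in the knockout. Only 15 of 35 myeloid and 6 of 18 B-lymphoid genes passed the count filter, which can keep a gene through the group where it is high. Of 15 myeloid genes 5 rose and 1 fell, or 8 and 1 adjusted over the list alone (median 0.79, adjusted p = 0.00342, and adjusted p = 0.284 with an estimated correlation). CEBPA, the master regulator of granulocytes, rose 12.9-fold to 12.6 ± 2.00 CPM (adjusted p = 5.61e-04), and CTSG, a neutrophil protease, had 129 reads against 3, a ratio of 40.4 (13.5 to 199). CTSG was lost without any unedited EV library or knockout EV replicate 1 (adjusted p up to 0.0786). All 3 B-lymphoid genes called of 6, also adjusted over the list alone, rose: CD79A, a B cell receptor chain, 38.2-fold, RAG2 14.0-fold and CD24 2.53-fold to 629 ± 30.1 CPM (list median 2.57, adjusted p = 0.00219, and adjusted p = 0.0918 with an estimated correlation). CD24 was lost without knockout EV replicate 1 (adjusted p = 0.0537). NF-kB genes were higher, with 5 of 23 past the threshold and 7 adjusted over the list alone (median 0.28, adjusted p = 0.00156, and adjusted p = 0.43 with an estimated correlation), and the list was lost without knockout EV replicate 1 (adjusted p = 0.0509). Of these ICAM1 rose 4.87-fold (adjusted p = 0.00108) and TNFAIP2, a cytokine-induced protein, 5.91-fold (adjusted p = 0.016). TNFAIP2 was lost without unedited EV replicate 2 (adjusted p = 0.0812) or 4 (0.0509) or knockout EV replicate 1 (0.0737).

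Platelet and transcription factor genes moved one by one, without their lists. PLEK, the platelet kinase C substrate, rose 3.61-fold to 307 ± 30.3 CPM (SD, n = 3), SLC24A3, a calcium exchanger, rose 150-fold, CD36, a scavenger receptor, fell 4.21-fold and LAT, a signalling adaptor, fell 1.48-fold (adjusted p = 5.47e-05, 6.01e-05, 0.005 and 0.00522). ZBTB16, a zinc finger repressor, rose 8.89-fold (adjusted p = 0.00286). FLI1 and ETS1, both ETS factors, rose 2.58-fold and 5.14-fold (adjusted p = 0.0405 and 0.0301), but FLI1 was lost without every library except knockout EV replicate 2 (adjusted p up to 0.19), and ETS1 without unedited EV replicates 2 and 3 and knockout EV replicates 1 and 4 (up to 0.15). 6 further lists were called by camera and lost with an estimated correlation. Mast cell genes were higher (1 of 13 rose, as adjusted over the list alone; median 1.09, adjusted p = 0.0425, and adjusted p = 0.341 with an estimated correlation). Interferon genes were higher as a set (2 of 43 rose and 1 fell, 3 and 1 adjusted over the list alone; median 0.15, adjusted p = 0.0382). OAS3, an antiviral enzyme, rose 2.46-fold while IFI27, an interferon-induced protein, fell 10.1-fold, and IFI27 was lost without knockout EV replicate 1 (adjusted p = 0.0574) or 4 (0.0643). Unfolded protein response genes were higher (median 0.19, adjusted p = 0.0382; edgeR 0 of 26, 2 adjusted over the list alone, 8 at an unadjusted p under 0.05, DESeq2 3, limma-voom 0). Stress genes were lower (1 of 18 fell, 2 adjusted over the list alone; median -0.15, adjusted p = 0.0382); these 3 lists had adjusted p = 0.666 with an estimated correlation. G1/S genes were lower (1 of 41 fell, 0 adjusted over the list alone; median -0.08, adjusted p = 0.0413, and adjusted p = 0.666 with an estimated correlation), as were MYC and ribosome biogenesis genes (1 of 30 fell, MYC itself by 0.63; 1 rose and 1 fell adjusted over the list alone; median -0.08, adjusted p = 0.0479, and adjusted p = 0.716 with an estimated correlation). Each of these 6 was lost without 3 of the 6 libraries, among them unedited EV replicate 2 for all 6 (adjusted p up to 0.439); MYC was lost without each of the 6 (up to 0.184).

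ETV6 against EV in knockout cells asks what adding ETV6 back does. Many genes that were high in the knockout fell. CLIC5 dropped from 226 ± 27.7 to 1.06 ± 0.214 CPM (SD, n = 3; log2 -7.72, SE 0.61, adjusted p = 1.74e-05), LMTK3 59.2-fold, BIRC7 35.5-fold to 1.26 ± 0.609 CPM, and CD79A 24.2-fold. KRT9, a keratin, KNDC1, a Ras exchange factor, and DSC3, a desmosome protein, fell 31.5-fold, 25.8-fold and 14.9-fold. CD24 fell 5.59-fold to 113 ± 21.8 CPM and ICAM1 5.61-fold (adjusted p = 2.48e-04 and 9.10e-04). WAS fell 2.00-fold, NBEAL2 1.55-fold and SEL1L, of the endoplasmic reticulum degradation pathway, 1.41-fold (adjusted p = 0.00117, 0.00476 and 0.00267). Among the rises, SGK1, a serum-induced kinase, rose 3.22-fold, NR4A2, a nuclear receptor, 2.25-fold, GFI1B, a repressor needed for megakaryocytes and red cells, 1.54-fold and DIAPH1 1.37-fold (adjusted p = 0.00329, 9.08e-04, 0.00403 and 4.75e-04). STC1, a secreted glycoprotein, rose 5.05-fold (adjusted p = 0.0282), but its call was lost without every library except ETV6 replicate 4 (adjusted p up to 0.123).

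224 genes passed, 31 higher and 193 lower, and with the replicate number as a block in these 6 libraries 2904 passed, 1273 higher and 1631 lower, including all 224. The count was 148 without knockout EV replicate 1, 139 without EV replicate 4, and 132, 144 and 139 without ETV6 replicates 1, 2 and 4. Of the 406 genes higher in the knockout, 89 fell with ETV6 (243 with the block) and 6 fell with R369W, which was tested without a block; of the 125 lower ones, 8 rose with ETV6 (40 with the block) and 0 with R369W by edgeR. The median change of the 406 genes was 1.48 in the knockout, -0.48 with ETV6 and -0.09 with R369W. The 406 genes were chosen as high in the knockout EV libraries, which are the baseline of both vectors. Some fall with either vector can therefore arise without an effect. SLFN11 averaged 55.1 ± 41.7 CPM with EV and 41.5 ± 32.3 with ETV6, and HLA-B 93.1 ± 23.9 and 85.8 ± 16.3; these genes were chosen here after their values were seen.

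The myeloid list was lower: 2 of 15 genes fell, 4 adjusted over the list alone (median -0.70, camera adjusted p = 5.17e-07, and adjusted p = 0.0208 with an estimated correlation). CD33 fell 2.92-fold to 122 ± 10.9 CPM (SD, n = 3) and ITGAM 4.04-fold (adjusted p = 4.30e-06 and 1.96e-04). CD33 averaged 327 CPM in unedited and 356 in knockout EV cells, and ITGAM 110 in each, so their fall did not undo a rise in the knockout. Of the myeloid genes named as higher in the knockout, CEBPA averaged 12.6 CPM with EV and 10.3 with ETV6, and CTSG 2.52 and 0.505. B-lymphoid genes were lower, with CD79A, CD24 and RAG2 falling of 6 genes, also 3 adjusted over the list alone (median -1.32, adjusted p = 1.23e-04, and adjusted p = 0.0208 with an estimated correlation). RAG2 fell 3.63-fold (adjusted p = 0.0373) and was lost without each of the 6 libraries (adjusted p up to 0.166). Stress genes were higher (18 genes, median 0.40, adjusted p = 7.55e-06, and adjusted p = 0.691 with an estimated correlation), as were cholesterol synthesis genes (25 genes, median 0.24, adjusted p = 0.00211, and adjusted p = 0.905 with an estimated correlation). edgeR called 0 genes of either, 5 and 0 adjusted over the list alone, 8 and 2 at an unadjusted p under 0.05, DESeq2 3 and 0, limma-voom 0. The EV libraries of these lists had more unaligned reads (0.527% to 0.809% against 0.279% to 0.349%). MYC and ribosome biogenesis genes were higher as a set (median 0.10, adjusted p = 0.034, and adjusted p = 0.905 with an estimated correlation), while the 1 gene called of 30, also adjusted over the list alone, fell: WDR12, a ribosome assembly factor, by 0.32. This list was lost without EV replicate 1 (adjusted p = 0.0882), ETV6 replicate 2 (0.224) or ETV6 replicate 4 (0.0906), and WDR12 without each of the 6 libraries (up to 0.17).

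R369W against EV in knockout cells asks what the variant adds back. Without a block 6 genes fell by edgeR: FCHSD2, a regulator of actin and endocytosis, dropped 2.37-fold from 252 ± 51.8 to 106 ± 1.2 CPM (SD, n = 3; log2 -1.25, SE 0.13, adjusted p = 9.05e-04), and EZH2, the methyltransferase of Polycomb complexes, 2.01-fold from 238 ± 5.71 to 119 ± 15.5 CPM (adjusted p = 0.00389). ZDHHC3, a palmitoyltransferase, fell 1.78-fold, CD79A 10.5-fold, MIB1, a ubiquitin ligase, 1.91-fold and LNPEP, an aminopeptidase, 1.39-fold (adjusted p = 0.00545, 0.0271, 0.0268 and 0.0271). With ETV6, which rose, 7 genes passed, against 1695 at an unadjusted p under 0.05, 195 called by DESeq2 and 1339 with 4 surrogate variables (516 higher, 823 lower), a model chosen after the data were seen. The count was 3 without knockout EV replicate 1 or R369W replicate 2, 4 without EV replicate 2, EV replicate 4 or R369W replicate 4, and 11 without R369W replicate 1. CD79A was lost without each of the 6 libraries (adjusted p up to 0.291), MIB1 and LNPEP without every one but R369W replicate 1 (up to 0.217 and 0.227), and ZDHHC3 without EV replicate 1 (0.0536) or R369W replicate 2 (0.0648).

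By camera 3 lists were higher in this comparison: cholesterol synthesis (25 genes, median 0.30, adjusted p = 0.00244), stress (18 genes, median 0.27, adjusted p = 0.0161) and cytoskeleton and proplatelet formation (45 genes, median 0.10, adjusted p = 0.034), and each had adjusted p = 0.963 with an estimated correlation. All 3 tools called 0 of their genes, as did adjustment over each list alone, with 8, 2 and 5 at an unadjusted p under 0.05. Without R369W replicate 4 the 3 lists had adjusted p = 0.05, 0.0778 and 0.179; without R369W replicate 1 stress and cytoskeleton both had 0.0674, and cytoskeleton had 0.0689 without EV replicate 2. The EV libraries of this comparison had more unaligned reads as well.

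R369W against ETV6 in knockout cells compares the variant with ETV6 in cells labelled as an ETV6 knockout. Several of the genes that fell most with ETV6 were higher with R369W, but CD79A, DSC3 and DPEP1, a membrane dipeptidase, did not pass (adjusted p = 0.401, 0.244 and 0.13), and CD79A averaged 11.8 CPM with EV, 0.477 with ETV6 and 1.11 with R369W. CLIC5 averaged 164 ± 16.5 CPM against 1.06 ± 0.214 (SD, n = 3; log2 7.26, SE 0.61, adjusted p = 4.38e-05), MYT1 was 69.1-fold, LMTK3 49.8-fold, BIRC7 37.4-fold and KRT9 35.5-fold higher. CD24 was 5.31-fold, RINL 5.36-fold, ICAM1 4.54-fold and CCDC88B, a protein of immune cell migration, 6.65-fold higher (adjusted p = 4.91e-04, 9.49e-06, 0.00327 and 4.97e-04). WAS was 2.53-fold, IFITM2 2.32-fold and NBEAL2 1.78-fold higher (adjusted p = 1.46e-04, 0.00798 and 7.80e-04), and IFITM2 was lost without ETV6 replicate 4 (adjusted p = 0.0571). SGK1 was lower by 3.40-fold, NR4A2 by 1.95-fold, SPRED1, an inhibitor of Ras signalling, by 1.85-fold, SLC20A1, a phosphate transporter, by 1.81-fold and DIAPH1 by 1.27-fold (adjusted p = 0.00327, 0.00571, 0.00798, 0.00391 and 0.00571). In this comparison 151 genes passed, 131 higher and 20 lower. The count was 91, 100 and 89 without ETV6 replicates 1, 2 and 4, and 57 without the knockout libraries numbered 4 and 10, whose library numbers are out of order.

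The myeloid list was higher with R369W than with ETV6, with 2 of 15 genes higher and 5 adjusted over the list alone (median 0.89, camera adjusted p = 3.94e-08, and adjusted p = 0.0239 with an estimated correlation). The 2 were CD33, by 2.76-fold, and ITGAM, by 3.52-fold (edgeR adjusted p = 9.49e-06 and 7.07e-04). Of 6 B-lymphoid genes CD24 and RAG2 were higher than with ETV6, also adjusted over the list alone (median 0.99, camera adjusted p = 0.00747, and adjusted p = 0.0801 with an estimated correlation). The list was lost without R369W replicate 4 (adjusted p = 0.0594). Against knockout EV cells edgeR called none of these genes higher with R369W. CD24 averaged 629 CPM with EV and 598 with R369W, CD33 356 and 337, ITGAM 110 and 96.0, and RAG2 8.15 and 9.60. RAG2 was 4.28-fold higher (adjusted p = 0.0231) and was lost without ETV6 replicate 2 or 4 or R369W replicate 4 (adjusted p up to 0.126).

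**Figure D4:**
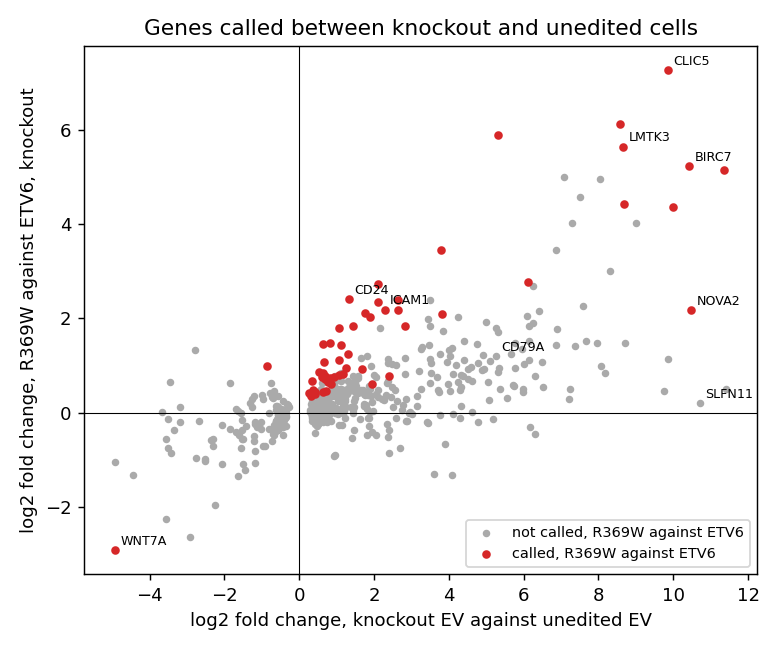
Log2 fold change of the 531 genes called between knockout and unedited EV cells (x axis) against their log2 fold change between R369W and ETV6 in knockout cells (y axis), comparisons that share no library. Red genes were also called on the y axis: 53 of the 406 genes on the right were called higher with R369W than with ETV6.

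Comparisons without shared libraries overlapped. Of the genes called in the knockout and between R369W and ETV6 in knockout cells, 53 were higher in both, against 4.34 from the product of the counts, among them CLIC5, CD24 and ICAM1, and 1, WNT7A (chosen here after its values were seen), was lower in both, against 0.204. The log2 changes correlated across genes at r = 0.41 (Spearman 0.16); genes are not independent replicates. The overlap was 33 without knockout ETV6 replicate 2, and 1 gene was called in opposite directions with all libraries in. With R369W against ETV6 in unedited cells the knockout shared 49 higher genes, against 4.57, and 1 lower (r = 0.36, Spearman 0.20). In that pair 2 genes were called in opposite directions. ETV6 lowered 34 genes in both genotypes, against 0.551, including CD24, RINL, CD33 and WAS, and raised ETV6 and DIAPH1 in both (r = 0.49, Spearman 0.49). That overlap of 36 was 23 without unedited EV replicate 2, 11 without EV replicate 3, and 16 and 17 without unedited ETV6 replicates 2 and 3. R369W raised 1 gene, ETV6, in both genotypes (r = 0.08, Spearman 0.20). A set of 32 genes fell with ETV6 and was higher with R369W than with ETV6 in both genotypes, and 12 of these were also higher in the knockout. Unlike the overlaps above, these calls share the ETV6 libraries of each genotype, and the 12 also share EV libraries. Shared noise can add to both counts, and no value for unchanged groups was computed for them.

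In comparisons that share the EV libraries, shared noise alone gives a correlation. ETV6 and R369W moved 1 gene together in unedited cells, the vector gene ETV6 (r = 0.04, covariance 0.00437) and 7 in knockout cells (r = 0.38, covariance 0.0565). Unchanged groups simulated with shared libraries gave covariances of 0.1 and 0.0996 with the dispersion between lines and 0.0114 and 0.0110 with that within lines. Libraries were drawn independently. Where libraries of a line vary together, line differences largely cancel between vectors, so the between-line values overstate the shared noise. Against the within-line values, from the dispersion of the 9 unedited libraries, the covariance was lower in unedited and higher in knockout cells. The 7 genes were ETV6, CD79A, FCHSD2, EZH2, ZDHHC3, MIB1 and LNPEP, and the number was 3 without knockout EV replicate 1 or R369W replicate 2 and 4 without EV replicate 2, EV replicate 4 or R369W replicate 4. Knockout and add-back of ETV6 moved 97 genes in opposite directions, 89 higher and then lower, against 6.39 (covariance -0.205, simulated -0.0993 and -0.0108), and 2 in the same direction. The 6.39 takes the comparisons as independent, but both use the knockout EV libraries. The 20 simulations gave at most 0 such genes. They held no changed genes, so they cannot show how many of the 97 come from shared libraries. The overlap of 97 was 56 without knockout EV replicate 1, 53 without EV replicate 4 and 61 without ETV6 replicate 2.

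Whether a vector's effect differed between genotypes was tested by interaction. The effect of ETV6 differed for FCHSD2, ZDHHC3 and EZH2 and that of R369W for 5 genes, with values in the closing part. The difference between R369W and ETV6 differed between genotypes for 0 genes by edgeR, with 124 at an unadjusted p under 0.05 and 0 by DESeq2 and limma-voom. With the replicate number as a block, 138 genes passed for ETV6, 63 higher and 75 lower.

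Lists of megakaryocyte and platelet genes, the focus of the cell line's lineage, did not pass in any of the 7 comparisons. The smallest camera adjusted p was 0.284 for 37 megakaryocyte and platelet genes and 0.346 for 19 megakaryocyte transcription factors. Camera tests a shift of a list in a common direction and can miss a list whose members move both ways. In the knockout PLEK and SLC24A3 rose while CD36 and LAT fell, so these values do not exclude such a mixed change. ITGA2B, the platelet integrin chain, averaged 986 ± 125 CPM (SD, n = 3) in unedited EV cells and 1180 ± 161 in knockout EV cells, and was chosen after its values were seen. Smallest adjusted p values for other lists were 0.108 for ETS factors, 0.0745 for G2/M, 0.066 for glycolysis and hypoxia, 0.408 for p53 targets, 0.331 for stem and progenitor genes, 0.623 for 4 stromal and epithelial genes and 0.0772 for 5 T and NK cell genes. The median log2 changes of these lists lay between -0.27 and 0.56.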

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

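Of the tests in this part, the splits of the libraries were chosen only after the results were seen. In 8 cases the change with a vector differed between knockout and unedited cells by the interaction test of edgeR. With ETV6, FCHSD2 fell by 2.03 on the log2 scale in knockout and by 0.24 in unedited cells (difference -1.79, SE 0.19, adjusted p = 9.66e-04); it averaged 252 CPM in knockout EV cells and 61.8 with ETV6, against 40.4 to 54.2 in the unedited groups. ZDHHC3 changed by -1.43 and 0.00 (difference -1.44, SE 0.16, adjusted p = 9.66e-04). EZH2 changed by -1.41 and 0.01 (difference -1.42, SE 0.18, adjusted p = 0.00417), with 238 CPM in knockout EV cells and 89.8 with ETV6.

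With R369W, MYT1 changed by 0.02 in knockout and was fitted 6.92 higher in unedited cells (difference -6.89, SE 0.79, adjusted p = 0.0108), where EV cells held 1 read, so this size depends on the prior count. FCHSD2 changed by -1.25 and 0.19 (difference -1.43, SE 0.19, adjusted p = 0.0118). CLIC5 changed by -0.46 and 6.08 (difference -6.54, SE 0.88, adjusted p = 0.0172). ZDHHC3 changed by -0.83 and 0.24 (difference -1.07, SE 0.16, adjusted p = 0.0172), and EZH2 by -1.01 and 0.12 (difference -1.12, SE 0.18, adjusted p = 0.0364). Without 1 library the 5 calls became 1 (unedited EV replicate 2, knockout EV replicate 4), 2 (unedited EV replicate 4, unedited R369W replicate 2, knockout EV replicate 1), 3 (unedited EV replicate 3, unedited R369W replicate 3, knockout R369W replicate 4) or 0 (knockout R369W replicate 2). MYT1 was lost without knockout R369W replicate 2 (adjusted p = 0.059), and FCHSD2 without that library, unedited EV replicate 2 or knockout EV replicate 4 (up to 0.059). CLIC5, ZDHHC3 and EZH2 were lost without 8, 7 and 11 of the 12 libraries (up to 0.0997, 0.0832 and 0.135).

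Of 24 splits of the libraries, 1 gave at least as many genes as the 5 called for R369W, the real one, and the highest other gave 1. These splits did not keep replicate numbers apart, and the count was 0 without the knockout libraries numbered 4 and 10, so whether chance is excluded stays open for it. For ETV6, 2 of 24 splits gave at least the 3 called, and the highest other gave 154. That split keeps the knockout EV libraries apart from the knockout ETV6 libraries and mixes only the unedited ones, so it carries the effect of ETV6 in knockout cells and is no test of chance; the other 22 gave 0 by edgeR. Whether chance is excluded is left open. For R369W against ETV6 all 24 splits gave the real 0 by edgeR (124 genes at an unadjusted p under 0.05; DESeq2 0, limma-voom 0), with 0 as the highest other.

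For each of the 7 comparisons of 2 groups, 1 of 10 splits of the 6 libraries, the real one, gave as many genes, and the other splits gave at most 0 by edgeR. These splits are too few for a share under 0.05. The real counts were 37, 3 and 147 in unedited cells (ETV6 and R369W against EV, and R369W against ETV6), 531 between genotypes, and 224, 7 and 151 in knockout cells.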

How the results depend on the processing

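The block within paired libraries and the 4 surrogate variables were chosen only after the results were seen. Counts are given in the order unedited ETV6 against EV, R369W against EV, R369W against ETV6; knockout against unedited EV; and the same 3 comparisons in knockout cells. DESeq2 called 91, 13, 287, 893, 401, 195 and 362 genes, and 13 and 14 for the interactions of ETV6 and R369W. With only the groups compared, edgeR called 2, 1, 35, 211, 131, 0 and 73, and 1 for the R369W interaction. limma-voom called 1 for unedited R369W against EV. With the replicate number as a block over all 18 libraries the counts were 80, 8, 356, 979, 748, 266 and 486. That block does not follow the knockout R369W libraries, which correlated at -0.581 to -0.153 with same-numbered knockout libraries. The 979 also takes a number shared by both genotypes as 1 source, which is not known. Lists and overlaps with this block carry the same limits. With the block in paired libraries they were 956, 251, 1980 and, in knockout cells with ETV6, 2904, with 138 for the ETV6 interaction. With 4 surrogate variables they were 664, 154, 1594, 3426, 2535, 1339 and 2312, and 103, 124 and 21 for the interactions of ETV6, R369W and R369W against ETV6; between genotypes these variables can absorb differences among lines, which are its replicate error. Without the knockout libraries numbered 4 and 10 edgeR called 132, 3 and 57 in knockout cells and 0 for the R369W interaction. The cause of these shifts was not tested.

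Lists called with an estimated correlation numbered 0, 0, 2, 0, 2, 0 and 1. With the block over all libraries 7 were called between genotypes, 8 for knockout ETV6 against EV and 4 for knockout R369W against ETV6. With the paired block the numbers were 8 and 9 for unedited R369W against EV and ETV6 and 8 for knockout ETV6 against EV, and without libraries 4 and 10 it was 0 for knockout R369W against EV. Overlaps with the block over all libraries were 152 (knockout with R369W against ETV6 in knockout cells), 73 (ETV6 between genotypes), 132 (knockout with R369W against ETV6 in unedited cells), 93 (ETV6 and R369W in knockout cells) and 224 (knockout and add-back, opposite). Without libraries 4 and 10 the first was 22 and the fourth 3.

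Leaving out 1 library at a time, calls ranged over 11 to 41, 2 to 6, 90 to 131, 246 to 577, 132 to 161, 3 to 11 and 89 to 130, and over 3 to 3, 0 to 6 and 0 to 0 for the interactions. Lists ranged over 2 to 8, 2 to 9, 2 to 11, 5 to 11, 4 to 7, 0 to 5 and 1 to 4. Overlaps ranged over 33 to 58, 11 to 39, 35 to 50, 3 to 8 and 53 to 85 in the order above, and 1 to 1 for R369W between genotypes and for ETV6 and R369W in unedited cells. The log2 change of ETV6 ranged over 4.45 to 5.08, 4.51 to 5.14, -0.03 to 0.19, -0.47 to 0.24, 4.19 to 4.83, 3.97 to 4.61 and -0.40 to -0.06. It was -0.0257 without unedited R369W replicate 3, 0.24 without unedited EV replicate 4 and 0.16 without knockout EV replicate 2.

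Of the named genes 0 turned direction among those called by edgeR. Without 1 library 306 of 996 values lost their call, with limma-voom 26 of 158, with only the groups compared 81, without libraries 4 and 10 42, with no filter 16, with a stricter filter 1 of 154, and with the other settings 0. Of the 35 lists called, 30 lost their call with an estimated correlation, 4 with the block over all libraries and 3 without libraries 4 and 10; without 1 library 50 of 210 values did.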

Other observations

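All genes of this part were chosen after their values were seen, as were the tests except that of exchanged vector labels and that of chromosomes. Some genes that fell with ETV6 take part in signalling; no list of such genes was tested. VAV1, an exchange factor downstream of antigen receptors, averaged 112 ± 26.9 CPM with EV, 51.7 ± 8.72 with ETV6 and 192 ± 24.5 with R369W in unedited cells (SD, n = 3; edgeR adjusted p = 0.0402 for ETV6 against EV), and 234 ± 41.6, 74.0 ± 2.63 and 258 ± 79.3 in knockout cells (adjusted p = 4.32e-04). PIK3CG, a phosphoinositide kinase, averaged 81.7 ± 11.3, 39.3 ± 3.90 and 119 ± 4.26 CPM in unedited cells and 128 ± 3.25, 51.5 ± 5.98 and 109 ± 3.29 in knockout cells. SYK, a tyrosine kinase of immune and platelet receptors, went from 85.0 ± 10.5 to 49.1 ± 6.13 CPM with ETV6 in unedited cells (adjusted p = 0.00894). PROS1, the anticoagulant protein S, went from 124 ± 23.8 to 38.8 ± 8.53 CPM with ETV6 in knockout cells (adjusted p = 8.09e-05).

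With the replicate number as a block, 312 genes passed as higher with ETV6 in unedited and 1273 in knockout cells, and the 4 named here are examples that passed in both and in neither without the block. TFPI2, an inhibitor of coagulation proteases, rose by 1.85 in unedited and 3.64 in knockout cells (log2; SE 0.27 and 0.31, n = 3, edgeR adjusted p = 3.44e-04 and 8.94e-06 with the block, and 1 and 0.134 without). SERPINB2, a plasminogen activator inhibitor, rose by 1.86 and 3.10, and NTS, the precursor of neurotensin, by 1.46 and 4.08 with the block. EGR1, an immediate-early transcription factor, rose by 0.94 and 1.51.

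The knockout R369W libraries did not pair with the other knockout libraries by number. Vector labels exchanged between the knockout ETV6 library numbered 4 and the knockout R369W library numbered 10 are argued against, because their scores on the genes that part R369W from ETV6 in unedited cells differed by 0.763, with -0.482 and 0.281. Line numbers exchanged among the knockout R369W libraries may explain it: with the libraries labelled 1, 2 and 4 read as 2, 4 and 1, the lowest of 6 correlations was 0.739. No biological explanation was tested.

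The EV libraries had more unaligned reads in both genotypes. As a separate batch they would have moved R369W and ETV6 cells alike, but the 644 genes that fell with ETV6 in unedited cells (median -0.43 with the block) had a median change of 0.104 with R369W, and 183 of them fell. This argues against a batch for those genes as a set. For the stress and cholesterol lists a batch and an effect of both vectors cannot be told apart, since the smallest adjusted p between R369W and ETV6 was 0.0628 and the EV libraries carry the library numbers 13 to 18. Neither list passed for R369W against EV in unedited cells (adjusted p = 0.346 for each).

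Of the 406 genes higher in the knockout, 317 were not called back with ETV6. The block called 48.6% of them back (154 genes), but the 317 genes were chosen as high in the same EV libraries that this test uses. It left 163, with a median change of 1.40 in the knockout and -0.11 with ETV6, and 14 genes rose further with ETV6 in it. For the 317 genes as a set the share does not decide between a missed return and a lasting difference. A copy number change of a whole chromosome is argued against, since 0% of the 317 genes lay on a chromosome with a median change beyond 0.3, and medians ran from -0.06 to 0.09 over 23 chromosomes. A difference between the lines that is unrelated to ETV6 stays open.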
